A study of Homo sapiens with 4 samples.

How the data were processed

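Substrates were made by in vitro transcription from synthesized DNA templates, per the labels' protocols, and incubated with purified Microprocessor and SRSF3 in 10 µl with 500 mM NaCl and 2 mM MgCl2. Product RNA was ligated to adapters that carry 6 degenerate bases, reverse-transcribed and amplified, while input RNA was reverse-transcribed with custom primers and amplified, so the preparation of the libraries differs between the groups. The submitters' processing notes name cutadapt 2.3 and Bowtie2 2.2.4 without saying what each was used for. The reference, the read filters and any use of the degenerate bases to remove duplicates are not given in the sources used here, so reads may not be independent molecules.

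The deposited input table holds whole-number counts of reads per pri-miRNA and library. The deposited product table holds estimated counts per pri-miRNA, start and end position, in 750962 rows; values are fractions where pri-miRNAs have near-identical copies, whose reads the authors' counting divided. Identical copies hold the same value in the input table, so a copy's ratio is not on the same footing as that of a single pri-miRNA. In all, 282 pri-miRNAs share reads with copies, 272 of them with fractional values, which hold 1.31% and 1.46% of product reads. Sums of estimated counts were rounded to whole numbers before testing. The deposited input lists 1881 pri-miRNAs and the products list 1880 of them. The start and end positions run from 1 to 125 and were used as deposited. The labels give 125 as a number of sequences, but 125 was read as the substrate length, on which the fragment classes rest.

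From the product table, fragments were classed by position: precursor-like (both ends at least 5 nt inside the substrate, 40 to 90 nt long), 5' flank (starting within 5 nt of the first base, ending by position 59) and 3' flank (ending within 5 nt of the last base, starting from position 66). Precursor-like fragments numbered 2059592 and 5396423. These were summed per pri-miRNA and compared with the input in edgeR 4.0.16 (R 4.3.3; TMM normalization, quasi-likelihood test, no block), for 1818 pri-miRNAs with at least 10 reads in each input library; 63 were left out. Values are log2 ratios with standard errors from the fit and Benjamini-Hochberg adjusted p-values, called under 0.05. The 2 replicates of each group differed by more than the counting error of reads (chi-square per degree of freedom 109 for input and 443 for products), so they were not merged; this does not show that they were prepared separately. With a pair of libraries per group, precision is limited. Data were simulated for 1811 pri-miRNAs from the input profile, with known changes in the products and the same fitted spread in both groups. The test recovered 3.57% of those changed 2-fold, 14.5% of those changed 4-fold and 95.9% of those changed 16-fold, with 4 false calls among 1613 unchanged. The real product libraries differed more than the input libraries, so these rates hold only for data that follow the fitted model. No outlier test or regrouping of samples was made, since groups of 2 are too small for either.

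The lists of pri-miRNAs, the comparison of low- and high-numbered names, the site measures, the neighbour pairs and the rule for named pri-miRNAs were fixed before the data were examined. The 19 lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over the lists. With the correlation estimated from the data 0 of 19 passed the threshold and 0 had an unadjusted p under 0.05. These estimates rest on 4 libraries and ranged from -0.452 (let-7 group I) to 0.9996 (capped precursors). A list not called with them is therefore not shown to be unshifted. Differences of medians over pri-miRNAs were tested two-sided by 100000 permutations (Python 3.11.15, numpy 2.4.6), where pri-miRNAs are the units and not replicates of the reaction. Site shares are the percent of a pri-miRNA's precursor-like fragments at its most used start or end, per product library, for those with at least 100 fragments in each. Intervals of shares are Wilson 95% intervals (SciPy 1.17.1). The named pri-miRNAs are the 12 highest and 12 lowest past the threshold with the same direction in both same-numbered pairs, the highest and lowest of each list, 13 chosen by name (mir-16-1, mir-15a, mir-144, mir-451a, mir-497, mir-195, mir-21, mir-30a, let-7a-1, mir-17, mir-320a, mir-484 and mir-877), the 6 most and 6 least uniformly cut with at least 1000 precursor-like fragments in each product library, and mir-142 and mir-9-1.

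Genome positions, host genes and hairpin sequences come from GENCODE 29 (GRCh38), matched by name for 1876 of 1881 pri-miRNAs; hairpins were folded with ViennaRNA 2.7.2 to find the apical loop. The sequences next to the hairpins were not used here, so the planned tests of the downstream CNNC motif and the basal UG motif were not run, and the search for UGU or GUG in the loop was made in their place. Alternatives planned beforehand were DESeq2 1.42.0 size factors, library totals, the DESeq2 Wald test, other input minimums (none, 50), all product reads, fragments of 50 to 75 nt, a replicate block, leaving out each library, an absolute log2 change above 1, and other minimums (20, 1000) and widths for the sites. Chosen after seeing the data were counts of 5' or 3' flank fragments, an input minimum of 1000, leaving out pri-miRNAs that share reads, and a permutation of list membership.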

Results

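Human primary microRNA transcripts (pri-miRNAs) are cut by Microprocessor, the complex of the RNase III enzyme DROSHA and its partner DGCR8, which frees a hairpin precursor from its 5' and 3' flanks. The study transcribed a pool of short pri-miRNA substrates in vitro and incubated 40 fmol of it with 200 fmol of purified Microprocessor and 20 pmol of SRSF3, a splicing factor that binds downstream of many hairpins, for 1 h at 37 °C. Samples named input, read here as the pool before the reaction, and samples named products were sequenced in 2 replicates each. The labels repeat the text on the reaction for all samples, so that the input was left uncut is a reading of its name. The input libraries held 31510715 and 31191065 reads over 1881 pri-miRNAs, with a median of 14488 and 14250 reads per pri-miRNA. The product libraries held 89176479 and 78578477 reads, each assigned to a pri-miRNA and to the first and last position of the fragment in the substrate, which runs from 1 to 125. The labels call the samples biological replicates but do not say how they were prepared separately, so the p-values measure the spread between these 4 libraries, which may be technical. Intervals and floors given here cover counting error only.

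The first question was where the substrates were cut. The products were mostly the flanks that the cuts release. Fragments from the substrate's 5' end made up 50.5% ± 0.209 (SD, n = 2) of product reads and fragments reaching its 3' end 40.8% ± 4.59 (SD, n = 2). Fragments with both ends at least 5 nt inside the substrate and 40 to 90 nt long, called precursor-like below, made up 2.31% of reads in replicate 1 and 6.87% in replicate 2. Molecules cut on one side only were a small part of reads: the precursor part still joined to the 3' flank was 0.73% ± 0.268 and the 5' flank still joined to the precursor part 0.571% ± 0.0311 (SD, n = 2). Whole substrates were 0.00141% and 0.00121% of reads, although many pri-miRNAs gave little precursor, so long molecules seem poorly recovered and these shares do not measure how common they were.

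The 5' flank ended most often at position 30, in 19.9% and 19.6% of 5' flank reads, and 68.6% ± 2.10 (SD, n = 2) of them ended between positions 27 and 32. The 3' flank started most often at position 91, in 22.7% and 21.6% of 3' flank reads, and 72.5% ± 2.13 (SD, n = 2) started between positions 89 and 94. Precursor-like fragments started most often at position 31 and ended most often at position 90 in both libraries, 1 nt inward of both flank positions.

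**Figure D1:**
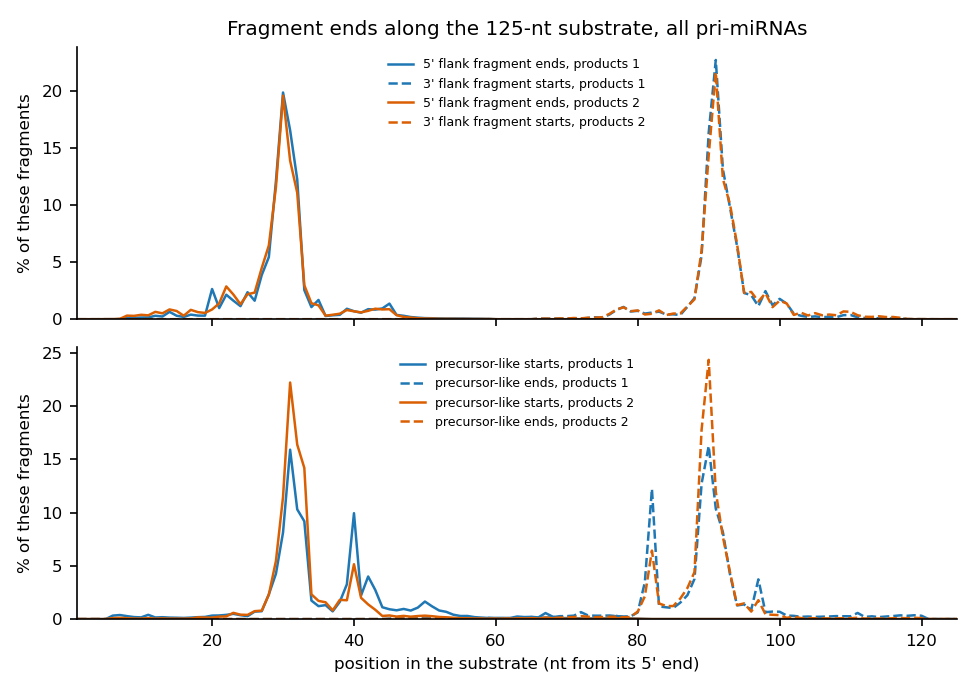
Percent of fragments (vertical axes) that end or start at each position of the substrate (horizontal axis, nt from its 5' end), in products replicate 1 (blue) and replicate 2 (orange). The upper panel shows ends of 5' flank fragments (solid) and starts of 3' flank fragments (dashed), with peaks at positions 30 and 91. The lower panel shows starts (solid) and ends (dashed) of precursor-like fragments, with peaks at positions 31 and 90 and smaller ones at 40 and 82, the most used ends of mir-4473.

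The precursor of most pri-miRNAs had a length near 60 nt. Among 1150 pri-miRNAs with at least 100 precursor-like fragments in each product library, the most used fragment had a median length of 59 nt (interquartile range 53 to 62). In 748 of them (65.04%) it was 55 to 66 nt long, and in 242 (21.04%) it was under 50 nt. All 15 members of the miR-17/92 clusters, a cell-cycle associated group of polycistronic miRNAs, fell in the range of 55 to 66 nt (median 61 nt), as did all 6 of the miR-30 family (median 62 nt). The 12 let-7 pri-miRNAs, regulators of developmental timing, stood outside it with a median of 73.5 nt (interquartile range 69.25 to 77). The let-7 group II members, whose precursors are known to need an added uridine before DICER cleavage, had a median of 75 nt over 9 pri-miRNAs. The group I members had a median of 67 nt over 3, of which 1 had a most used fragment under 50 nt. The miR-548 family had a median of 58 nt over 64 pri-miRNAs and the chromosome 19 cluster 59 nt over 46.

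The next comparison was how uniformly each hairpin was cut at its 5' and 3' side. At the 5' side the most used position took a median of 53.4% ± 10.4 of precursor-like fragments (SD of the library medians, n = 2; interquartile range over 1150 pri-miRNAs 35.3% to 75.4%). At the 3' side it took 56.8% ± 5.95 (interquartile range 36.6% to 79.5%). Replicate 1 had medians of 47.9% and 53.7% and replicate 2 medians of 62.6% and 62.1%. The mean share over pri-miRNAs was 54.6% at the 5' side and 56.4% at the 3' side, a difference of -1.80 percentage points (two-sided permutation test by sign flips over 1150 pri-miRNAs, p = 1e-05, the smallest that 100000 resamples can give). The difference was -3.43 points with at least 1000 fragments and -3.22 with flank fragments (permutation p = 1e-05 for each). It turned to 0.804 points without products replicate 1 (permutation p = 0.00363) and to 0.221 with fragments of 50 to 75 nt (permutation p = 0.527). The most used fragment was the same in both replicates for 842 of 1150 pri-miRNAs (73.2%, Wilson 95% interval 70.6% to 75.7%), and for 87.6% of those with at least 1000 fragments. The cut read from the precursor-like fragments was the cut read from the flank for 68.2% of 1145 pri-miRNAs at the 5' side and 71.4% at the 3' side.

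By their precursor-like fragments, some pri-miRNAs released nearly a single product. Among those with at least 1000 precursor-like fragments in each product library, the highest share in one fragment was that of mir-335 at 96.8% ± 1.29 (SD, n = 2; positions 32 to 89), an intronic miRNA of MEST. mir-144, which is active in red blood cell development, gave 95.8% ± 1.21 from 33 to 90. The near-identical mir-513a-1 and mir-513a-2, which share reads, gave 95.5% ± 3.34 and 95.4% ± 3.48 from 33 to 90. mir-4701 (96.7% ± 0.0689) and mir-635 (96.6% ± 0.469) completed the 6 highest with shorter fragments of 42 and 40 nt, starting at position 43. At the other end, mir-499a, mir-3074, mir-6509, mir-665, mir-4755 and mir-3116-2 had no precursor-like fragment above a mean share of 13.1%. The flanks, which are the larger part of the reads, kept the order of some of these hairpins and changed that of others. At the most used flank position of the 5' side, mir-335, mir-144 and mir-513a-2 stayed high (93.7%, 96.8% and 84.4%). mir-4755 stayed low there (26.8%). mir-3074 and mir-3116-2 (41.6% and 42.2%) lay near the median of 40.9% over 1836 pri-miRNAs. In contrast, mir-665 had 74.6% ± 2.29 and 86.1% ± 1.95 (SD, n = 2) at its 5' and 3' sides. mir-6509 had 51.2% at its 5' side and 83.2% ± 15.7 at its 3' side. mir-499a had 97.3% ± 1.15 at its 5' side, next to position 8, a cut seen in 0.0108% and 0.0326% of all 5' flanks. mir-513a-1 and mir-635 had only 26.8% ± 1.01 and 30.8% ± 4.23 at the 5' side, but 92.4% and 73.6% at the 3' side. mir-9-1, a neuronal miRNA, had 81.1% ± 3.68 in one fragment of 62 nt. mir-142, an abundant miRNA of blood cells, had 19.8% ± 16.5 in its most used fragment of 40 nt, a spread of the same order as its value. That fragment ran from 8 to 47. The flanks of mir-142 placed its most used cuts elsewhere, next to positions 33 (34.6% ± 10.8) and 89 (44.6% ± 1.04).

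The main quantity of each pri-miRNA, called yield below, was its share of precursor-like fragments in the products against its share of the input. It ranks hairpins by the precursor recovered, which mixes cutting with recovery. A freed precursor leaves both flanks, yet flanks were 50.5% and 40.8% of product reads and precursor-like fragments 4.59% (means). The order also changed with all product reads: mir-635 went from 4.14 to 0.05 on the log2 scale and mir-6509 from 0.67 to 4.44. Of 1818 pri-miRNAs with at least 10 reads in each input library, 378 were enriched in the products and 722 were depleted (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The log2 products/input value had a median of -0.80 and an interquartile range from -3.37 to 1.26, and 1622 of 1818 pri-miRNAs had the same sign in both same-numbered pairs. Across pri-miRNAs, which are not independent replicates, the values of the pairs correlated with r = 0.906. Input and product libraries were prepared in different ways, which goes with the comparison. These values are relative, and the scaling sets where 0 lies: the median was 0.07 with DESeq2 size factors (630 enriched, 549 depleted) and -1.47 with library totals (250 enriched, 826 depleted). With all product reads 743 were enriched and 832 depleted. The counts also moved with single libraries: 88 and 464 without input replicate 1, 80 and 454 without input replicate 2, 724 and 984 without products replicate 1, and 716 and 955 without products replicate 2.

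**Figure D2:**
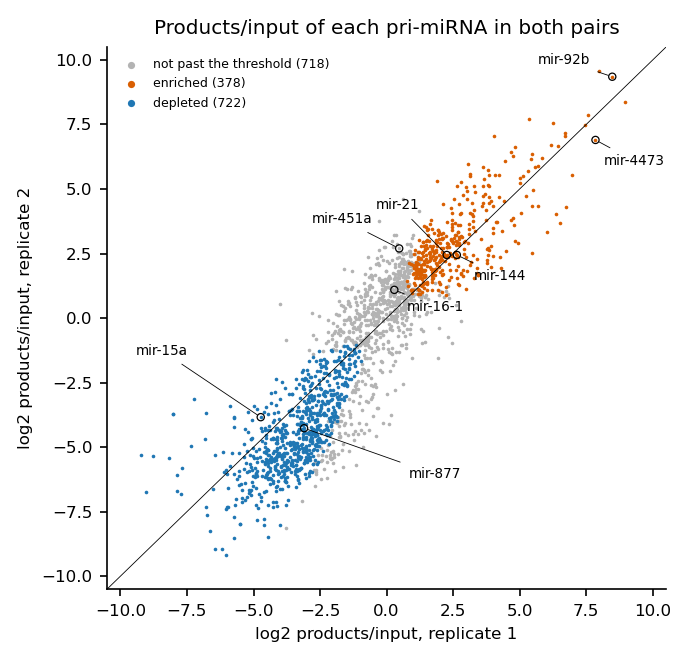
log2 products/input of each of 1818 pri-miRNAs in the replicate 1 libraries (horizontal axis) and the replicate 2 libraries (vertical axis), from CPM with TMM scaling plus 0.5. Each point is a pri-miRNA, coloured as enriched (378), depleted (722) or past no threshold, and the line marks equal values. Named pri-miRNAs are circled, with mir-92b and mir-4473 at the upper right and mir-15a and mir-877 at the lower left.

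The 12 highest ratios past the threshold ranged from 9.73 to 6.62 on the log2 scale. The highest was mir-92b at 9.73 ± 0.801 (SE; edgeR adjusted p = 0.00694), on chromosome 1 at 155195177 to 155195272 (GRCh38, exonic in an antisense transcript). It had 35 and 13 input reads against 859 and 2087 precursor-like fragments. mir-3199-2, mir-6503, mir-4776-1, mir-3130-2, mir-3922, mir-3199-1, mir-5688, mir-3160-2, mir-4471 and mir-4674 were also among the 12, and like mir-92b each had fewer than 1000 input reads in a library, so their ratios rest on a small denominator. Of these, mir-3199-2, mir-4776-1, mir-3130-2, mir-3199-1 and mir-3160-2 also share reads with near-identical copies and are uncertain. The exception in depth was mir-4473, in an intron of MLLT3 on chromosome 9 (20411148 to 20411238, minus strand), at 7.45 ± 0.728 (SE; adjusted p = 0.0071) from 19542 and 18846 input reads. It gave 196210 and 222169 precursor-like fragments, 90.9% ± 0.106 (SD, n = 2) of them the 43-nt fragment from 40 to 82. With only fragments of 50 to 75 nt counted its value was -1.05, and with all product reads 3.56. It fell below the threshold without input replicate 1 or 2 (lowest adjusted p = 0.0597). Without either input library 29 of the 81 named pri-miRNAs tested fell below the threshold in the same direction.

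Of the 12 lowest pri-miRNAs, all but mir-6886 had over 1000 reads in each input library, and they gave almost no precursor-like fragments. mir-3977 had 20002 and 19398 input reads and 9 and 2 precursor-like fragments, a log2 value of -7.65 ± 1.19 (SE; edgeR adjusted p = 0.0106). mir-3975 (-7.59 ± 0.573), mir-6128 (-7.53 ± 0.575) and mir-630 (-7.29 ± 0.514) had adjusted p = 0.00694 each. mir-2052, mir-1243, mir-4307, mir-1321, mir-1302-5, mir-1244-4 and mir-6081 lay between -7.64 and -6.82, and of these mir-1302-5 and mir-1244-4 share reads with copies. mir-6886 had 317 and 270 input reads and no precursor-like fragment in either product library, so it was at least 13.8-fold lower in the products than in the input (3 counts over both libraries as the floor).

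The lists of other conserved miRNAs and of muscle and neuron miRNAs lay above the rest of the pool, with wide ranges inside each list. Most of the rest were high-numbered pri-miRNAs, with a median of -2.18, compared further below with the low-numbered ones. The low-numbered ones had a median of 0.74, above that of the other conserved miRNAs (0.56) and below that of the muscle and neuron miRNAs (1.11). No list was tested against the low-numbered pri-miRNAs, so a difference from the rest does not set a list apart from that class. Of the 42 other conserved miRNAs, 14 were enriched and 2 depleted (13 and 1 when adjusted over the list alone), and their median was 1.44 above that of the other pri-miRNAs (camera, adjusted p = 0.00126 with a preset correlation of 0.01; adjusted p = 0.744 with an estimated correlation and 0.228 by permutation of membership). They ranged from mir-203a, a skin miRNA, at 3.87 ± 0.821 (SE) down to mir-221 at -2.40 ± 0.532 (SE). With all product reads mir-203a had 1.69 and mir-221 had 0.92. mir-21, a growth-associated miRNA at the 3' end of VMP1 on chromosome 17 (59841266 to 59841337), was enriched 5.13-fold (2.36 ± 0.317 on the log2 scale, adjusted p = 0.0085). Of the 19 muscle and neuron miRNAs, 8 were enriched and 2 depleted (7 and 1 adjusted over the list alone), with a median 1.96 above the rest (camera adjusted p = 0.0323; adjusted p = 0.744 with an estimated correlation). The call was lost without products replicate 2 (adjusted p = 0.0581), under library totals (0.0961), with the replicate block (0.0549), with no input minimum (0.0611), without pri-miRNAs that share reads (0.167) and by permutation of membership (0.228). In the first 5 of these the median still lay 1.57 to 1.94 above the rest. mir-132 was highest at 2.51 ± 0.465 and its cluster neighbour mir-212 lowest at -5.01 ± 0.945 (SE).

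The smaller conserved families were not past the threshold as lists with the main choices. The miR-17/92 clusters had 5 of 15 members enriched and 1 depleted (5 and 0 adjusted over the list alone; camera adjusted p = 0.0623, or 0.0471 without products replicate 1, 0.0267 with DESeq2 size factors, 0.0283 with all product reads and 0.0136 with fragments of 50 to 75 nt), from mir-106b at 3.01 ± 0.459 to mir-106a at -1.36 ± 0.462 (SE), which had 1.34 with all product reads, and with mir-17 at 0.66 ± 0.408. The miR-30 family had 3 of 6 enriched and 0 depleted (3 and 0 adjusted over the list alone; adjusted p = 0.0623, or 0.0400 with DESeq2 size factors), from mir-30a at 2.09 ± 0.307 to mir-30c-2 at -0.35 ± 0.421, or 0.45 without products replicate 2. The miR-10/100/125 family had 3 of 8 enriched and 1 depleted (3 and 1; adjusted p = 0.0817, or 0.0454 with DESeq2 size factors and 0.0364 with fragments of 50 to 75 nt), from mir-125b-2 at 3.24 ± 0.458 to mir-99b at -1.64 ± 0.439. The miR-200 family, which maintains epithelial identity, had 2 of 5 enriched and 1 depleted (2 and 1; adjusted p = 0.163): mir-429 was at 3.08 ± 0.478 and mir-200b at -2.82 ± 0.5, or 0.03 with all product reads.

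The miR-34 family with its mir-449 relatives, which includes p53 targets, had 1 of 5 enriched and 2 depleted (2 and 2 adjusted over the list alone; camera adjusted p = 0.658), from mir-449c at 1.56 ± 0.404 to mir-34a at -2.11 ± 0.414 (SE). With all product reads mir-449c was at 0.57 (edgeR adjusted p = 0.181) and mir-34a at -0.20 (adjusted p = 0.445). The miR-15/16 family had 1 of 8 enriched and 2 depleted (0 and 1; adjusted p = 0.727), with mir-503 highest at 1.05 ± 0.328 and mir-15a lowest at -4.25 ± 0.624. The miR-181 family had 3 of 6 enriched and 1 depleted (3 and 1; adjusted p = 0.612), from mir-181a-2 at 1.90 ± 0.334, which shares reads, to mir-181b-1 at -3.70 ± 1.07. Its median lay 0.27 above the rest, and -0.46 from it without products replicate 1. The miR-29 family had 0 of 4 enriched and 1 depleted (0 and 1; adjusted p = 0.994), from mir-29b-2 at 1.49 ± 0.678 to mir-29c at -4.05 ± 0.537. For this list the median lay 0.74 above the rest while camera's direction was down, and the difference was -0.08 without products replicate 2.

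Of the 12 let-7 pri-miRNAs, 2 were enriched and 2 depleted (2 and 2 adjusted over the list alone), with a median 1.21 above the rest (camera adjusted p = 0.305). Their median of 0.38 lay below that of the low-numbered pri-miRNAs (0.74). With all product reads, of which flanks are the larger part, the list passed the threshold (2.33 above the rest, adjusted p = 0.00692). Group I had 2 of 3 enriched and 0 depleted (3 and 0; adjusted p = 0.0817), from let-7c at 2.65 ± 0.661 to let-7a-2 at 0.88 ± 0.316 (SE). Group II had 0 of 9 enriched and 2 depleted (0 and 0; adjusted p = 0.787, or 0.0251 with all product reads, 2.15 above the rest), from let-7f-2 at 0.60 ± 0.327 to let-7i at -1.49 ± 0.342, or 0.08 with all product reads. let-7a-1 was at 0.49 ± 0.352 by precursor-like fragments and at 3.08 by all product reads (edgeR adjusted p = 0.273 and 0.000546).

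The large primate-specific groups had medians above that of the rest of the pool, though 21 of 46 members of the chromosome 19 cluster and 48 of 72 of the miR-548 family passed no threshold. In the chromosome 19 cluster, a placental miRNA cluster, 24 of 46 pri-miRNAs were enriched and 1 depleted (23 and 1 adjusted over the list alone). Their median lay 2.33 above the rest (camera adjusted p = 1.61e-08; adjusted p = 0.744 with an estimated correlation). mir-527 was highest at 4.36 ± 0.535 and mir-516b-2 lowest at -2.19 ± 0.361 (SE), or 1.08 and -2.36 with all product reads. In the miR-548 family, whose hairpins derive from a transposable element, 20 of 72 were enriched and 4 depleted (18 and 4 adjusted over the list alone). The median lay 2.37 above the rest (camera adjusted p = 1.42e-05; adjusted p = 0.744 with an estimated correlation). The family ranged from mir-548az at 6.25 ± 1.26, with only 741 and 714 input reads, to mir-548o at -6.06 ± 0.547. With all product reads the chromosome 19 median was 1.22, below that of let-7 (2.201) and of the other conserved miRNAs (1.71). Members of both groups resemble each other: 44 of the 46 and 47 of the 72 share reads with copies, so single members are uncertain. Without pri-miRNAs that share reads the chromosome 19 cluster had 2 members left (adjusted p = 0.184), and the miR-548 family 25 (adjusted p = 0.0246). The chromosome 14 cluster, an imprinted miRNA cluster, had 11 of 42 enriched and 7 depleted (10 and 7; camera adjusted p = 0.0839). It ranged from mir-376a-1 at 3.29 ± 0.388, which shares reads, to mir-758 at -5.48 ± 0.436. The camera adjusted p was 0.0454 with DESeq2 size factors, 0.00692 with all product reads and 0.0131 with fragments of 50 to 75 nt. It was 0.209 under library totals, 0.325 without pri-miRNAs that share reads and 0.885 with an estimated correlation. The median of this cluster lay 1.90 above the rest without products replicate 1 and 1.05 without products replicate 2. With the main choices it was 0.52, below the 0.74 of the low-numbered pri-miRNAs. The medians of the chromosome 19 cluster (1.41) and the miR-548 family (1.38) lay above that value. With all product reads the low-numbered median was 1.34, above that of the chromosome 19 cluster (1.22) and below that of the miR-548 family (1.53).

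Hairpins known to be made without DROSHA, or from other structured RNAs, had medians below that of the rest of the pool. All 7 snoRNA-derived pri-miRNAs were depleted (7 also when adjusted over the list alone), with a median difference from the rest of -3.47 (camera adjusted p = 0.0294; adjusted p = 0.744 with an estimated correlation, 0.0538 under library totals and 0.0689 by permutation of membership). mir-664b, in DKC1, was at -6.46 ± 0.496 and mir-3653 at -2.34 ± 0.593 (SE). Of 12 mirtrons, short introns whose hairpins are released by splicing, 0 were enriched and 9 depleted (0 and 10 adjusted over the list alone). The median difference from the rest was -2.81, and the list just missed the threshold (camera adjusted p = 0.0623). The camera adjusted p was 0.0412 with DESeq2 size factors and 0.0267 with an input of at least 1000. It was 0.0962 with fragments of 50 to 75 nt, 0.0997 under library totals, 0.136 without pri-miRNAs that share reads and 0.744 with an estimated correlation. By permutation of membership it was 0.0689. The difference was -2.82 and -2.79 without input replicate 1 or 2, and -3.06 and -2.27 without products replicate 1 or 2. mir-1227 was lowest at -5.01 ± 1.07 and mir-1237 highest at 1.73 ± 0.748, which did not pass the test. mir-877, in an intron of ABCF1 on chromosome 6 (30584332 to 30584417), was depleted 12.2-fold (-3.61 ± 0.582 on the log2 scale, adjusted p = 0.0114). The capped precursors mir-320a and mir-484, whose ends are set by transcription, were at -2.05 ± 1.07 and -1.87 ± 1.13, 0 of 2 past the threshold on their own or adjusted over the list alone (camera adjusted p = 0.658). Their pairs lay apart, at -1.18 and -4.37 for mir-320a and -0.946 and -4.36 for mir-484, and the list difference was -3.48 without products replicate 1 and -0.094 without products replicate 2. With all product reads both were depleted (-2.81, edgeR adjusted p = 0.00131, and -3.25, adjusted p = 0.00613). Most of the mirtrons and of the snoRNA-derived pri-miRNAs are high-numbered, a class with a median of -2.18 and 50.3% depleted. The medians of these lists, -3.60 and -4.26, lay below that value. Neither was tested against that class, so much of their distance from the rest may go with it.

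**Figure D3:**
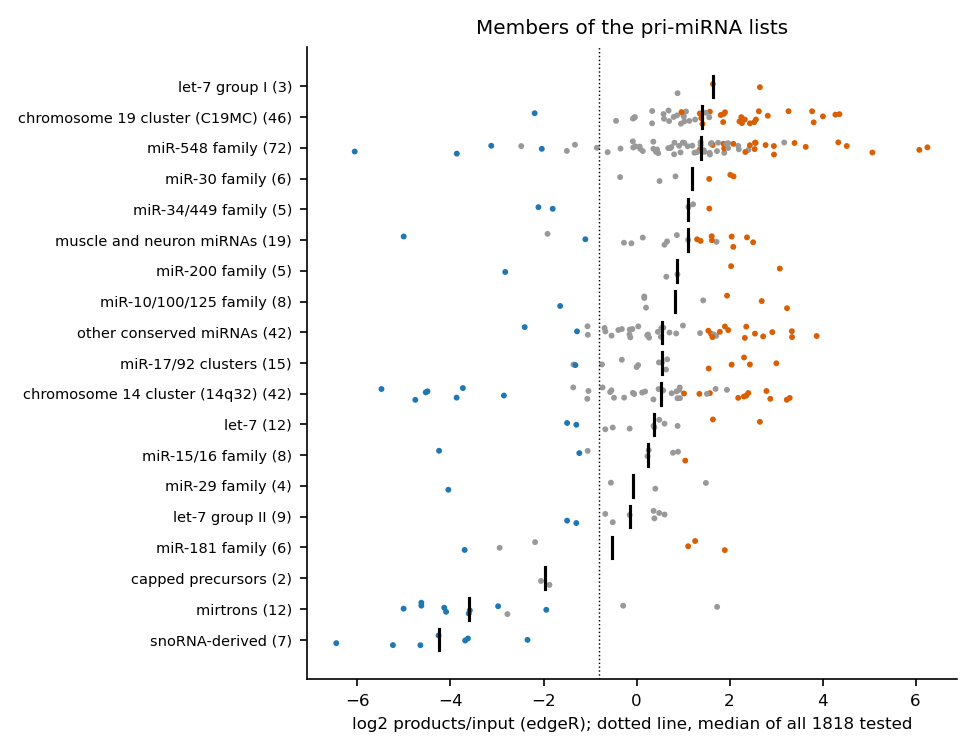
log2 products/input (horizontal axis, edgeR) of each member of the pri-miRNA lists, with the number measured in brackets. Points are pri-miRNAs, orange where enriched, blue where depleted and grey where past no threshold; black bars are list medians and the dotted line is the median of all 1818 tested, -0.80. The snoRNA-derived and mirtron medians lie lowest and the chromosome 19 and miR-548 medians near the top.

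pri-miRNAs named early and late in the catalogue of human miRNAs differed widely. Names are numbered in order of annotation, and high numbers come mostly from deep sequencing. The 596 low-numbered pri-miRNAs (let-7 and numbers below 800) had a median log2 products/input of 0.74, and the 1186 high-numbered ones (from 1000) a median of -2.18. The difference of 2.92 had a two-sided permutation p = 1e-05 over pri-miRNAs, the smallest that 100000 resamples can give. Of the low-numbered pri-miRNAs, 181 (30.4%) were enriched and 110 (18.5%) depleted, against 189 (15.9%) and 597 (50.3%) of the high-numbered ones. Among pri-miRNAs with at least 100 precursor-like fragments in each product library, 496 of the low-numbered and 632 of the high-numbered, the low-numbered were also cut more uniformly by the flank fragments, with a median share at the most used position of 73.3% at the 5' side and 85.9% at the 3' side, against 45.2% and 49.3%. Their most used precursor fragment was 55 to 66 nt long in 80.8% of them, against 52.1% of the high-numbered ones. Neither contrast was tested, and the minimum leaves out more of the high-numbered pri-miRNAs. The high-numbered group was not uniform: its members numbered from 4000 had a median of -2.69 and those from 2000 up to 4000 a median of -0.15.

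**Figure D4:**
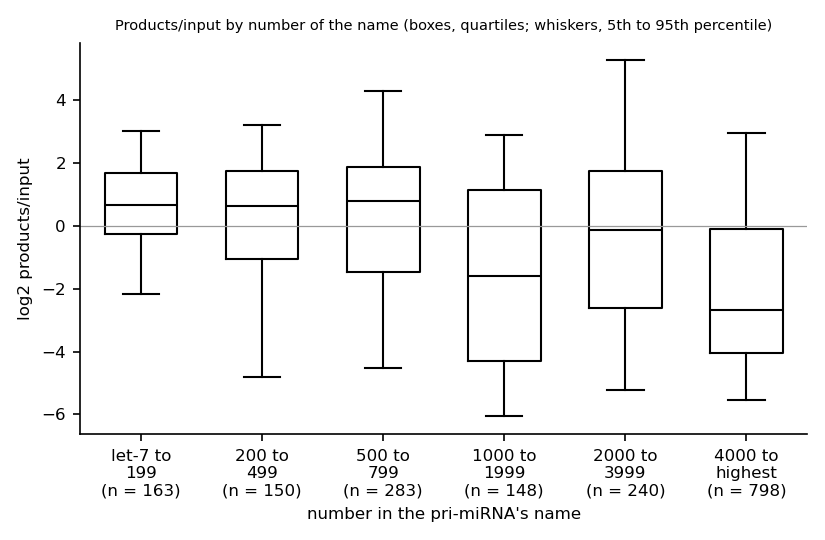
log2 products/input (vertical axis) by the number in the pri-miRNA's name (horizontal axis, with the number of pri-miRNAs in each class). Boxes span the quartiles with the median as a line, and whiskers reach from percentile 5 to 95. The medians of the classes numbered below 800 lie above 0 and those from 1000 lie below 0, lowest (-2.69) from 4000 up.

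Of the 3 pairs of neighbouring hairpins chosen for comparison, here cut as separate substrates, 1 showed very different yields. mir-132 and mir-212, and mir-29b-2 and mir-29c, are further neighbours. They were named above as the highest and lowest of their lists, so their distance follows from that choice. mir-15a and mir-16-1, which lie in DLEU2 on chromosome 13 (50049119 to 50049201 and 50048973 to 50049061, minus strand), are known for the dependence of mir-15a on its neighbour in cells. mir-16-1 exceeded mir-15a by 4.94 ± 0.0651 on the log2 scale (SD, n = 2 pairs), or 30.7-fold, with precursor-like fragments, and by 3.96 with all product reads. That SD understates the error, since the values of mir-16-1 and mir-15a had SDs of 0.405 and 0.470 and same-numbered libraries showed no pairing. mir-15a itself was depleted 18.97-fold (-4.25 ± 0.624, SE; edgeR adjusted p = 0.00956), from 3564 and 4179 input reads and 5 and 27 precursor-like fragments. mir-16-1 was at 0.79 ± 0.513 (adjusted p = 0.235), or 1.55 with all product reads (adjusted p = 0.00154). Its 3' and 5' sides had 81.7% ± 2.11 and 39.5% ± 1.05 (SD, n = 2) of precursor-like fragments at the most used position, but 97.3% ± 0.974 and 85.0% ± 6.65 of flank fragments.

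mir-144 and mir-451a lie together on chromosome 17 (28861533 to 28861618 and 28861369 to 28861440, minus strand). mir-451a is known for a short hairpin that is matured by AGO2 in place of DICER. mir-144 was enriched 5.84-fold (2.55 ± 0.314, SE; edgeR adjusted p = 0.00781) and mir-451a was at 2.00 ± 0.847 (adjusted p = 0.101), or 2.65 with all product reads (adjusted p = 0.00898). Their difference, 0.96 ± 1.71 (SD, n = 2 pairs), was within the spread, with 2.16 in the pair of replicate 1 and -0.25 in that of replicate 2. The difference was 0.19 ± 1.29 with all product reads, 1.43 ± 0.604 with 5' flank and -0.28 ± 1.69 with 3' flank fragments. The cuts of mir-451a lay farther inside the substrate: its 5' flank ended at position 40 in 78.7% ± 12.8 and its 3' flank started at position 83 in 78.0% ± 3.57 of fragments, leaving a precursor from 41 to 82 of 42 nt. For mir-144 the positions were 32 (96.8% ± 0.563) and 91 (97.2% ± 1.31). mir-497 and mir-195, on chromosome 17 at 7017911 to 7018022 and 7017615 to 7017701 (minus strand), differed by 0.87 ± 0.813 on the log2 scale (1.44 and 0.29 in the pairs) with precursor-like fragments. They differed by 0.46 ± 0.0119 with all product reads, 1.45 ± 0.624 with 5' flank and -0.53 ± 0.366 with 3' flank fragments. With 2 pairs and no test, no order of this pair is drawn.

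**Figure D5:**
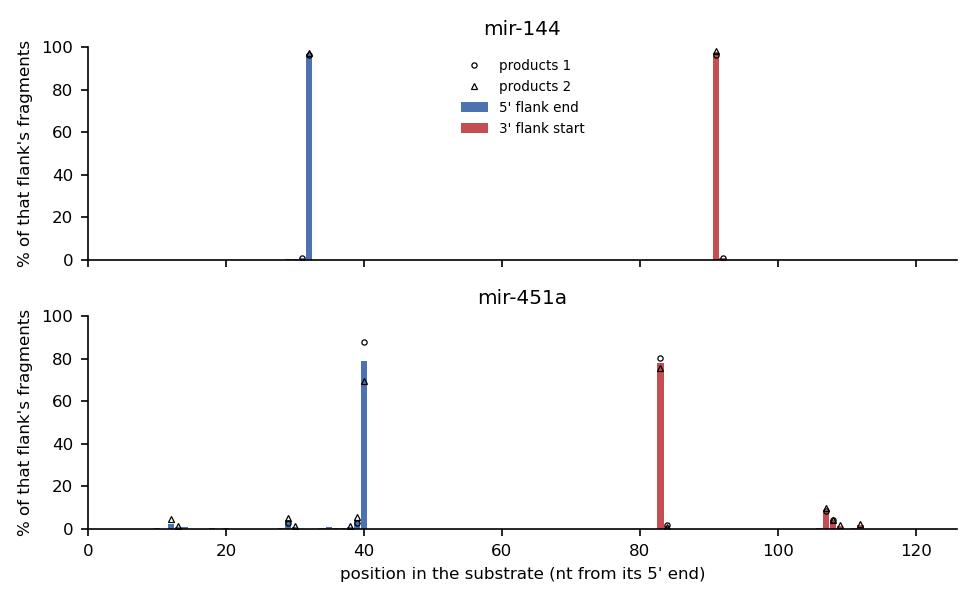
Percent of 5' flank fragments that end (blue) and of 3' flank fragments that start (red) at each position of the substrate (horizontal axis, nt from its 5' end) for mir-144 and mir-451a. Bars are means of the product libraries, and circles and triangles are replicates 1 and 2 where above 1%. The main cuts of mir-451a, at 40 and 83, lie inside those of mir-144, at 32 and 91.

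Of the sequence motifs linked to Microprocessor cutting, only the apical UGU or GUG was looked for, in the annotated hairpins. The search covered the predicted loop and the bases next to it. The 483 pri-miRNAs with the motif had a median log2 products/input 0.16 above that of 1332 without it (two-sided permutation test, p = 0.525). The difference was 0.54 with all product reads (permutation p = 0.111), and -0.12 among low-numbered pri-miRNAs alone (permutation p = 0.528).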

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

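Among the tests below, the comparison of other fragments of the same length and that with all product reads were chosen after the values they measure had been seen; the patterns were noticed in these data, and no biological explanation was tested, since the design sets only products against input.

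A few hairpins left out for lack of input reads gave many products. Of 63 pri-miRNAs with fewer than 10 reads in an input library, 5 had over 10000 reads in each product library. The medians of the pool were 10864 and 11554 product reads, so few of the 63 reached the middle of the pool. More than 3 reads in each product library, the limit that a count of 0 allows, were found for 58. Most of the pool passes that limit as well (lower quartiles 2745 and 3021). mir-625 had 8 and 12 input reads against 138674 and 122794 product reads, and mir-3150a had 4 and 2 against 101861 and 84264; these 2 were named after their values were seen.

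Among the tested pri-miRNAs, those with few input reads also had many products for their input. The 105 with under 1000 input reads in a library had a median log2 products/input of 3.46 against -1.09 for the others, a difference of 4.55. The split is on the denominator of the ratio, so a substrate under-read in the input falls in this group with a high ratio by construction, and the difference is no evidence of an excess of products. GC-rich hairpins read poorly in the input are argued against by a median GC only 0.578 percentage points higher. Counting noise is argued against by a median absolute difference of 0.330 on the log2 scale between the input replicates, far under the difference. Reads shared with copies are argued against by a share of 11.4% of these pri-miRNAs, against 15.2% of the others. Reverse transcription with custom primers in the input libraries alone may under-read some substrates, but it goes with the group and cannot be told apart from a real excess.

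Products replicate 2 held 2.97 times the share of precursor-like fragments of replicate 1, and 4.09 times at 55 to 66 nt. Better recovery of that length was set against other fragments of 55 to 66 nt, whose ratio was 0.737. By definition these keep a substrate end, so the comparison cannot separate length from the type of end and decides nothing. A few abundant pri-miRNAs as the cause are argued against by a ratio of 3.23 without the 20 most abundant. Inner fragments under 40 nt were also higher in replicate 2 (ratio 2.77), precursor parts still joined to the 3' flank were lower (0.588), and 5' flanks still joined to the precursor part nearly unchanged (0.926). A more complete reaction, a ligation that favoured fragments with both ends cut, or recovery by length may lie behind this, and all stay open.

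Low-numbered pri-miRNAs exceeded high-numbered ones by 2.92 on the log2 scale. Hairpin GC content as the whole cause is argued against by a mean difference of 2.48 within GC deciles (SE 0.343, all 10 above 0, from 0.76 to 3.54), above the bound of 1.95 set beforehand, though high-numbered hairpins are richer in GC (53.8% against 45.7%). The choice of fragment window is argued against by a difference of 3.11 with all product reads, the input level by a mean of 3.05 within input deciles (SD 0.966), and shared reads by 2.86 without pri-miRNAs that share them. The composition of the flanks, and substrates placed off-centre on the true hairpin, stay open.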

How the results depend on the processing

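Flank fragments, an input minimum of 1000, leaving out pri-miRNAs that share reads, permutation of list membership and the loop motif were chosen after seeing the data. The cause of the changes below was not tested, except where fewer libraries or fewer pri-miRNAs make the change.

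Counts of enriched pri-miRNAs moved from 378 to 630 with DESeq2 size factors, 250 with library totals, 680 with the DESeq2 Wald test, 743 with all product reads, 694 with 5' flank and 644 with 3' flank fragments. Leaving out 1 library gave 80 to 724 enriched and 454 to 984 depleted, where the lone sample of a group is assumed to vary like the other group. Of all calls, the enriched were 34.4% by the main scaling, 53.4% with DESeq2 size factors, 23.2% with library totals, 50.3% with the Wald test (672 depleted) and 47.2% with all product reads. Of the 1100 calls, 997 kept their direction and call with all product reads and 22 were called in the opposite direction; with 5' and 3' flank fragments 954 and 950 kept them and 27 and 30 were opposite, and without input replicate 1 only 539 kept them, and fewer without input replicate 2. The counts stayed within 1.5 times under the other alternatives. With the replicate block 341 were enriched and 767 depleted; deviations of same-numbered libraries did not go together (r = -0.0781), so the numbers show no pairing, and the block changed no list call but that of the muscle and neuron miRNAs (adjusted p = 0.0549).

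The number of lists past the threshold was 5, and 10 with DESeq2 size factors, 3 with library totals, 9 with all product reads, 8 with fragments of 50 to 75 nt, 0 with an estimated correlation (lowest adjusted p = 0.744), 10 with 5' flank and 9 with 3' flank fragments, 11 with an input of at least 1000, 3 without pri-miRNAs that share reads, 2 by permutation of membership (the chromosome 19 cluster, adjusted p = 0.0109, and miR-548, 0.00114) and 4 to 8 without 1 library. The miR-181 family, in no case called, turned to -0.49 with all product reads, -0.46 without products replicate 1 (0.895 without replicate 2), -0.86 with 5' flank fragments and -1.50 without shared reads, and the miR-29 family to -0.0792 without products replicate 2 (1.38 without replicate 1).

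Low- minus high-numbered kept its sign and call in the 9 alternatives run for it (2.23 to 3.74), which include no other scaling, length window, block or Wald test. The 5' and 3' site shares were 41.0% and 41.7% with at least 20 fragments, 71.4% and 77.3% with 1000, 73.1% and 73.6% for 50 to 75 nt, 65.2% and 70.6% within 1 nt and 40.9% and 43.6% with flank fragments; without products replicate 2 they were 43.4% and 48.2% and without replicate 1 60.1% and 59.8%. Their difference turned from -1.80 to 0.221 points (50 to 75 nt) and ranged from -2.91 to 0.804 without 1 replicate. The same fragment was most used in both replicates for 55.2% (20), 87.6% (1000), 86.8% (50 to 75 nt), 75.9% (within 1 nt) and 58.9% (flanks). mir-16-1 minus mir-15a was 3.96 with all product reads, 3.31 with 5' flank and 5.14 with 3' flank fragments, and mir-497 minus mir-195 -0.53 with 3' flank fragments. The motif difference was -0.12 for low-numbered pri-miRNAs.

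Named pri-miRNAs that changed sign: with all product reads let-7i 0.081, mir-106a 1.34, mir-30c-2 0.22, mir-200b 0.0302, mir-221 0.92, mir-17 -0.37, mir-3074 -0.93 and mir-4701 -0.45; for 50 to 75 nt mir-4473 -1.05, mir-451a -3.003, mir-6509 -0.92, mir-665 -0.0044, mir-4755 -1.08, mir-635 -2.55 and mir-4701 -5.78, whose main fragments but for mir-665 and mir-4755 are shorter than 50 nt; with library totals let-7f-2 -0.10, mir-195 -0.52, let-7a-1 -0.20, mir-17 -0.0619, mir-6509 -0.0459, mir-4755 -0.55 and mir-142 -0.19; with DESeq2 size factors or the Wald test mir-30c-2 0.52; with the replicate block mir-4755 -0.0036. Without products replicates 1 and 2 in turn, mir-30c-2 was -0.847 and 0.45, mir-195 0.822 and -0.38, and mir-4755 -0.56 and 0.966. Without an input library 29 of the 81 named pri-miRNAs tested lost their call, and none changed sign. The CNNC and basal UG tests and their alternatives were not run.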

Other observations

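The window used for the inner cuts below was chosen after the positions had been seen, and the drawing of 100 fragments after rho had. mir-451a was not alone in being cut farther inside its substrate. Among 1135 pri-miRNAs with at least 1000 fragments of each flank in each product library, 48 (4.23%) had at least 50% of their 5' flanks ending at positions 38 to 46 and at least 50% of their 3' flanks starting at positions 76 to 84 in both replicates. They include 11 of 491 low-numbered and 37 of 624 high-numbered pri-miRNAs; 9 of the 48 share reads with copies, so the same cuts can be counted under several names. Ordered by the lowest of their 4 shares, the first were mir-659 (98.1% ± 0.149 of 5' flanks and 97.2% ± 0.231 of 3' flanks; SD, n = 2), mir-548bb (97.6% ± 0.278 and 97.4% ± 0.55) and mir-583 (94.3% ± 1.60 and 94.2% ± 1.73). mir-451a had 84.2% ± 9.83 and 79.9% ± 3.996. mir-659, mir-548bb and mir-583 were named after their values were seen.

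Hairpins with a higher yield were cut more uniformly. Across 1139 pri-miRNAs, which are not independent replicates, the share at the most used 5' position rose with log2 products/input (Spearman's rho 0.440, permutation p = 0.0001, the smallest 10000 resamples can give; Pearson's r 0.413). With the 5' flank fragments and their own ratio rho was 0.718 over 1802 pri-miRNAs. Drawing 100 fragments per pri-miRNA and product library gave a rho of 0.439 but moved the shares hardly at all, so it decides nothing about the number of fragments, which is also the numerator of the ratio. A constant background of random fragments, which makes up more of the reads where little is cut, would give the same sign and was not tested. Both stay open.

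A higher yield with UGU or GUG in the predicted apical loop was predicted as a difference of medians above 0.5, and the value was 0.163 on the log2 scale, under the bound of 0.25 set for its absence. With all product reads it was 0.538 (permutation p = 0.111), above the predicted size but not past the threshold, and without replicates 1 and 2 in turn 0.427 (permutation p = 0.185) and 0.122 (permutation p = 0.625), so a higher yield is neither shown nor excluded. The test used predicted loops of annotated hairpins, which may differ from the loops the enzyme meets.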
